A study of Mus musculus with 8 samples.

How the data were processed

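The data are peak lists from ChIP-seq of Mgea5, Panx2 and Polr1c in primary mouse hippocampal neural progenitor cells, with a list for each of 2 replicates per protein. Per the labels' protocols, cells were fixed with formaldehyde, chromatin was sonicated, and libraries were made with a NEBNext kit and size selected. The submitters' processing notes name Trim Galore, Bowtie2 2.3.5, MACS3 3.0.0a5 and the mm10 build. The control given to the caller, its cut-offs, the read depth and any filter on duplicates or repeats are not given in the sources used here. The Mgea5 and Panx2 lists have the broad peak layout and the Polr1c lists the narrow peak layout. In the deposited values, the lowest −log10 p was 1.00 to 1.01 in the broad lists and 2.00 in the narrow lists, so the lists hold many positions with little enrichment. The input libraries were not used here.

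For each peak the authors deposited a fold enrichment, a ratio of ChIP to background pileup in MACS output, and a −log10 p and a −log10 q. These values are the authors' and were used only to describe, rank or filter peaks within a list. Because cut-offs and list lengths differ between lists, a higher number of peaks or a higher fold in a list is not a stronger signal of that protein. Broad calling at a lenient cut-off covers much of the genome (13.3% and 10.4% of the span for Mgea5, 4.64% and 11.9% for Panx2), so an overlap has meaning only against shifted lists. The narrow Polr1c lists cover far less, 0.0110% and 0.290%. Peak names carry a run directory, from which 2 calling runs were read, and the peak numbers of each list ran without a gap.

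Groups, comparisons, thresholds, gene lists and most alternative settings were fixed before the data were examined. Peaks on the 21 main chromosomes were compared, and those on the mitochondrial genome and other contigs were left out. Lists were compared by the share of the peaks of the shorter list that overlap the longer list by at least 1 bp, against 1000 circular shifts along each chromosome, a one-sided permutation test. Alternatives used 200 shifts, and for gene ends and gene classes a call was judged on the two-sided p, which is 2 times the smaller tail. The shift was applied to the shorter list, which gives the same relative positions. Shifts keep number, width and clustering of the peaks but not their neighbourhoods, and their p-values ask only whether positions coincide. Shared controls could not be simulated from peak lists.

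Genes came from the GRCm38.p6 RefSeq table, whose coordinates are those of mm10, with 49943 genes on the main chromosomes, of which 21887 are protein-coding and 1228 are microRNA genes. The table has no strand, so a window of 1000 bp around both ends of each gene replaced the planned window around the transcription start site. A gene counted as carrying a peak when both replicates had a peak in the window. Gene lists with at least 8 protein-coding members were tested by two-sided Fisher exact tests against all other protein-coding genes, with Benjamini-Hochberg adjustment over 87 tests and a threshold of 0.05. The 29 lists covered cell types (neural progenitor, neuronal, astrocyte, oligodendrocyte, microglia, endothelial and mural), microRNA processing, reported miR-9 targets, O-GlcNAc and hexosamine metabolism, connexins and pannexins, RNA polymerases I and III, cell cycle, immediate early, Notch, Wnt, long synaptic, imprinted, Polycomb and Trithorax genes, and gene families chosen by symbol (ribosomal protein, Hox, histone, olfactory and vomeronasal receptor, Zfp, protocadherin, oxidative phosphorylation, proteasome, solute carrier). A further list held brain microRNA loci. Gene classes were compared with shifts in the gene and 200 bp on either side.

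For miR-9, the highest fold within 5 kb of each precursor was ranked among all microRNA genes of the same list, with no peak counted as 0, and the mean percentile of the 3 loci was set against 100000 random sets, one-sided. Named genes are, by a rule fixed in advance, the miR-9 loci with overlapping genes, the genes of the 3 proteins and Ogt, the 10 genes with the highest geometric mean fold at their ends per protein, up to 4 such members of each list past the threshold and up to 2 of other lists described, the 5 shared regions of highest fold per protein, and the brain microRNA loci. The single RNA polymerase III genes, the chromosome 14 genes, and regions and genes named at a q of at most 0.01 or in the closing section were chosen after their values were seen, and so were the shifted values for regions in both replicates and the search for RNA polymerase III genes at Polr1c peaks.

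Alternatives were a −log10 q of at least 2 or 5, lists of equal length (at most 5000 peaks), reciprocal overlap of 50%, other windows, leaving out each replicate, leaving out the sex chromosomes, and comparing only libraries with the same replicate number. Added after the data were seen were shifts of 20 to 200 kb, libraries of 1 calling run only, genes of at least 4 kb, and gene sets without olfactory and vomeronasal receptor genes or without X, Y and chromosome 14 beyond 42 Mb, and the alternatives of the differences between proteins. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. The methods were tested on simulated data: 2 of 40 pairs of unrelated lists of 20000 peaks had a p under 0.05, a planted overlap of 30% was recovered as 29.4% ± 0.338 (SD), and of lists of 100 genes among 21887, 10 of 10 with planted peaks and 0 of 10 others were called. Simulated peaks were placed uniformly along the chromosomes, and simulated gene lists were drawn at random. Error rates for clustered peaks, for lists as long as the broad ones and for neighbouring genes were therefore not tested.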

Results

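ChIP-seq, which sequences the DNA crosslinked to an immunoprecipitated protein, was carried out on primary neural progenitor cells from the hippocampus of male C57BL/6 mice. The proteins were Mgea5, the enzyme that removes O-GlcNAc from proteins (its gene is now named Oga), Panx2, a pannexin channel protein, and Polr1c, a subunit shared by RNA polymerases I and III. Each was profiled in 2 replicate libraries, and 2 libraries of input chromatin completed the 8 samples. Peak lists of the 6 ChIP libraries were analysed, on the mm10 build. The Mgea5 lists held 536877 peaks in replicate 1 and 521566 in replicate 2, the Panx2 lists 145405 and 478662, and the Polr1c lists 826 and 35927. Read depth and the input libraries were not analysed here, so these numbers do not compare the proteins. Nothing in the labels says that replicates came from separate cultures or animals, so the spread between them may be technical.

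Most listed peaks were weak. The median fold enrichment over background, which is the authors' value for each peak, lay between 1.71 and 1.84 in the 4 Mgea5 and Panx2 lists and was 3.05 and 2.75 in the Polr1c lists. Peaks with a q of at most 0.01 numbered 114 and 117 for Mgea5, 12 and 376 for Panx2, and 246 and 1407 for Polr1c, in replicates 1 and 2. The X chromosome carried few peaks, at 0.160 and 0.0992 times the density of the autosomes outside chromosome 14 in the Mgea5 lists. Chromosome 14 beyond 45 Mb was as sparse, at 0.155 and 0.0991 times that density for Mgea5, 0.0799 and 0.209 for Panx2, and 0.177 and 0.101 for Polr1c. The part of chromosome 14 before 40 Mb had 1.15 to 1.58 times the density of the other autosomes. Genes on the sparse part include Atg14, Rpph1, and Mir124a-1 and Mir17 of the brain microRNA list.

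**Figure D1:**
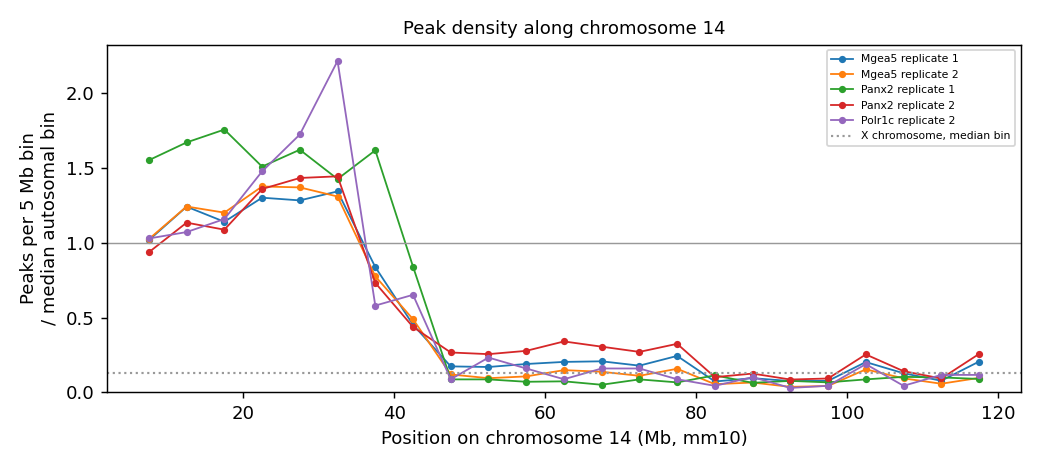
Peaks per 5 Mb bin along chromosome 14 (x axis, position in Mb on mm10), divided by the median autosomal bin of the same list (y axis), with a line for each of the 5 lists with enough peaks per bin. Density falls between about 35 and 45 Mb and stays near the level of the X chromosome (dotted, 0.132) to the end of the chromosome.

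The series title names the miR-9 genomic locus as the target, and the first comparison asked how the 3 miR-9 precursor loci ranked among annotated microRNA genes. miR-9 is a microRNA abundant in the developing brain. At Mir9-3 (chromosome 7, 79505264 to 79505353, inside the lncRNA gene Mir9-3hg and over the annotated microRNA gene Gm51285), both Polr1c lists had a peak. It spanned 79500605 to 79500910 in replicate 1, with a fold of 4.50 and a q of 0.0360, and 79500477 to 79500818 in replicate 2, with a fold of 2.59 and a q of 0.622. These peaks began 579 bp and 451 bp inside the low-coordinate end of Mir9-3hg (79500026 to 79534403) and ended 4353 bp and 4445 bp before the precursor. Neither Polr1c list had a peak within 5 kb of Mir9-1 (chromosome 3, 88215598 to 88215686, inside the lncRNA Gm3764 and over Gm25641) or Mir9-2 (chromosome 13, 83738814 to 83738885, inside the lncRNA C130071C03Rik and over Gm51268).

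Mgea5 peaks lay within 5 kb of all 3 loci in both replicates, with highest folds of 1.75 and 1.64 at Mir9-1, 1.64 and 1.76 at Mir9-2, and 1.77 and 1.89 at Mir9-3. The highest Panx2 folds were 1.71 and 1.83 at Mir9-1 and 1.76 and 2.37 at Mir9-3; at Mir9-2 replicate 1 had no peak and replicate 2 had a fold of 1.55. The lowest q among these Mgea5 and Panx2 peaks was 0.310, for Panx2 replicate 2 at Mir9-3. A nearby peak was common at this threshold: 91.4% and 83.5% of the 1228 microRNA genes had a Mgea5 peak within 5 kb, and 34.8% and 90.5% had a Panx2 peak. For Polr1c the shares were 0.977% and 21.7%, and Mir9-3 stood at percentiles 99.5 and 86.4 of the microRNA genes.

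Ranked together, the 3 loci did not stand above random sets of 3 microRNA genes in any list after adjustment over the 6 lists (one-sided permutation test, 100000 sets). The mean percentile was 32.9 and 51.9 for Mgea5 (permutation p = 0.84 and 0.46, adjusted p = 0.84 and 0.68) and 56.9 and 40.1 for Panx2 (p = 0.27 and 0.71, adjusted p = 0.68 and 0.84). For Polr1c it was 66.2 (permutation p = 0.017, adjusted p = 0.10) and 54.9 (permutation p = 0.38, adjusted p = 0.68), and Mir9-3 alone raised it. With windows of 1 kb the Polr1c mean of replicate 1 was 49.8, since its peak lies outside them. Across the 37 loci of the brain microRNA list, the mean percentile ranged from 50.9 for Polr1c replicate 1 to 58.7 for Panx2 replicate 2 (lowest adjusted p = 0.096, permutation test). Outside the miR-9 loci, the highest folds within that list were 2.58 for Mgea5 replicate 1 at Mir124a-3 (1.97 in replicate 2), 2.90 for Panx2 replicate 2 at Mir219a-1, and 3.70 for Polr1c replicate 2 at Mirlet7i. At the latter 2 loci replicate 1 of the same protein had no peak.

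**Figure D2:**
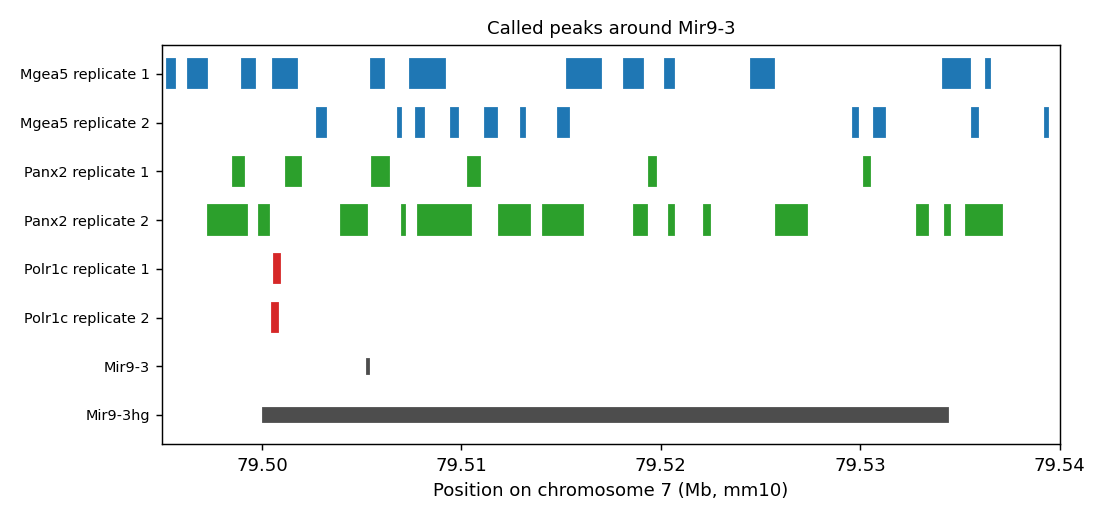
Called peaks of the 6 lists around Mir9-3 (x axis, position on chromosome 7 in Mb, mm10), with a track per list and the annotated extents of Mir9-3 and its host gene Mir9-3hg below. Both Polr1c lists have their peak near the low-coordinate end of Mir9-3hg, and the precursor lies at least 4353 bp away from it.

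The second comparison asked which sites each protein's replicates shared. For Mgea5 the highest shared folds were at an end of B4galt7, a glycosyltransferase gene of proteoglycan synthesis (chromosome 13, 55599768 to 55600205, folds 5.08 and 4.22), Kmt2a, a histone H3 lysine methyltransferase gene (chromosome 9, 44881318 to 44882517, folds 4.37 and 4.18), and Cpsf1, a gene of mRNA 3-prime end processing (chromosome 15, 76606560 to 76607639, folds 4.43 and 3.24). A region with no gene within 200 bp followed (chromosome 4, 67208506 to 67208678, folds 3.39 and 4.20). The fifth lay between Tapbp and Rgl2 (chromosome 17, 33929008 to 33930057, folds 3.40 and 3.97). Of the Mgea5 peaks in the shorter list, 37.0% overlapped the other list, against 26.2% after circular shifts (permutation p = 0.001, the smallest that 1000 shifts can give). The excess fell from 10.7 to 6.43 percentage points under shifts of 20 to 200 kb (30.6% expected). Among peaks with a q of at most 0.01, 66 regions were in both lists, and 62.1% of them touched an end of a protein-coding gene, against 5.41% after shifts. Over all peaks, overlap with Panx2 replicate 2 was similar: 41.7% against 28.3% for Mgea5 replicate 1 and 34.6% against 24.65% for replicate 2. The overlap over all peaks is therefore not particular to Mgea5. At a q of at most 0.01 the Mgea5 replicates overlapped more (61.1%) than either did with Panx2 replicate 2 (35.2% and 22.0%).

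For Polr1c the shared sites with the highest folds were each at an end of a protein-coding gene: Eps15, an endocytosis gene (chromosome 4, 109279972 to 109280383, folds 11.5 and 30.1), the kinetochore gene Cenpu (chromosome 8, 46551638 to 46552073, folds 22.8 and 12.4), Smarce1, a gene of the SWI/SNF remodelling complex (chromosome 11, 99230375 to 99230755, folds 10.7 and 21.6), the Integrator complex gene Ints10 (chromosome 8, 68793619 to 68794057, folds 15.2 and 14.3) and Timm22, a gene of mitochondrial protein import (chromosome 11, 76406874 to 76407397, folds 16.4 and 12.6). Of the replicate 1 peaks, 41.4% overlapped replicate 2, against 0.862% after shifts (permutation p = 0.001), a ratio of 48.0. This ratio was 24.5 under shifts of 20 to 200 kb, with 1.69% expected. Of the 325 regions in both lists, 84 touched a tRNA gene and 100 an end of a protein-coding gene. At a q of at most 0.01, 187 regions were shared, of which 52 touched a tRNA gene. Of the 187, 45 overlapped a Mgea5 peak of that q and 51 a Panx2 peak, against 0.016 and 0.022 after shifts. Both were overlapped by 43 regions and neither by 134. The Mgea5 and Panx2 lists are short at that q, and over all peaks 34 of the 325 regions overlapped neither protein.

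The Panx2 replicates shared no more positions than shifted lists, with 28.1% of replicate 1 peaks overlapping replicate 2 against 28.5% after shifts (permutation p = 0.98, ratio 0.985). The highest shared folds were 3.20 and 3.96 at chromosome 2, 173707574 to 173707843, where no gene lies within 200 bp, and 2.66 and 3.55 in the immunoglobulin heavy chain locus Igh (chromosome 12, 113424398 to 113424833). The next 3 regions had replicate 1 folds of 1.79 to 1.91, at chromosome 9, 78217684 to 78217967, at chromosome 2, 48714813 to 48715802, and in D630045J12Rik at chromosome 6, 38200311 to 38201290. Restricting the lists to a q of at most 0.01 turned the result, since all 11 replicate 1 regions of that q overlapped replicate 2 (permutation p = 0.005, the smallest that 200 shifts can give). All 11 also overlapped a peak of that q in at least 1 Mgea5 and at least 1 Polr1c list, and 7 did so in all 6 lists. Of these regions, 4 lay at the start of chromosome 9 (from 3000241 to 3038261), 5 lay within 10 kb of the last peak of chromosome 2, 7, 12, 14 or 18, and none touched an end of a protein-coding gene. Bp covered by both lists made up 11.3% of the bp covered by either for Mgea5, 3.64% for Panx2 and 1.46% for Polr1c.

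The third comparison was of sites shared between proteins. Polr1c regions in both replicates overlapped a Mgea5 peak in 263 of 325 cases, against 119.4 ± 9.88 (SD) after shifts, and a Panx2 peak in 222, against 88.0 ± 8.87 (permutation p = 0.001 for both). The sites at Eps15 and Smarce1 overlapped both, whereas those at Cenpu, Ints10 and Timm22 overlapped Mgea5 only. Of the 66 Mgea5 regions with a q of at most 0.01, 22 overlapped a Panx2 peak and 27 a Polr1c peak of that q, against 0.0090 and 0.045 after shifts (permutation p = 0.001 for both). Kmt2a and the Tapbp and Rgl2 site were among the latter. All 22 regions that overlapped a Panx2 peak were also among the 27, so at that q no region was shared by Mgea5 and Panx2 alone. Regions enriched in every list, such as those at the start of chromosome 9, can be among both counts: 7 of the 11 Panx2 replicate 1 regions of that q were in all 6 lists. The counts therefore do not separate sites of 2 proteins from regions common to all libraries. Over all peaks and the 4 pairs of libraries, the mean overlap was 44.9% against 19.3% after shifts for Mgea5 and Polr1c (mean ratio 2.31), 32.9% against 12.7% for Panx2 and Polr1c (2.65), and 35.1% against 28.3% for Mgea5 and Panx2 (1.25), each with a permutation p = 0.001. Peak names show 2 calling runs, with Panx2 and Polr1c replicate 1 in run A and the other lists in run B. Within runs the overlaps were 41.3% against 17.8% (ratio 2.29), 40.8% against 12.2% (3.67) and 38.1% against 26.5% (1.44), in the same order. The Mgea5 and Panx2 excess rested on Panx2 replicate 2: it was 9.92 percentage points without replicate 1 and 1.03 without replicate 2. Pairs with Panx2 replicate 2 lay within run B (ratios 1.47 and 1.40), and those with replicate 1 crossed runs (1.03 and 1.10). Replicate and calling run therefore cannot be told apart here. Under shifts of 20 to 200 kb the mean excess of 6.78 was 3.91. The pairs of Panx2 and Polr1c lists also differed, from 7.16% against 6.38% (ratio 1.12) for Panx2 replicate 1 with Polr1c replicate 2 to 32.1% against 7.17% (ratio 4.48) for both replicates 1. The former pair crossed runs and the latter lay within run A. The remaining pair across runs had a ratio of 2.13, and that within run B 2.86. Without replicate 1 the excess was 32.3 percentage points against a mean of 20.2. Part of each excess may come from input libraries shared as controls, which peak lists cannot separate.

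**Figure D3:**
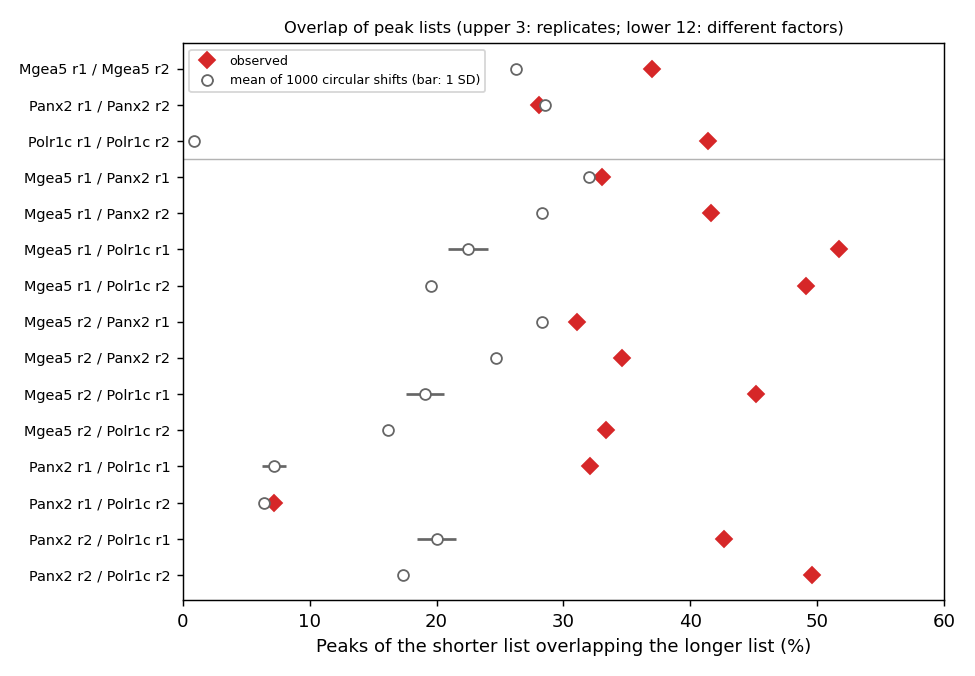
Share of the peaks of the shorter list that overlap the longer list (x axis, percent) for the 15 pairs of libraries, observed (diamonds) and after 1000 circular shifts (circles, mean; bars, 1 SD). Observed and shifted shares lie apart for the Mgea5 and Polr1c replicates (37.0% against 26.2% and 41.4% against 0.862%) and together for the Panx2 replicates (28.1% against 28.5%). For Mgea5 replicate 1 with Panx2 replicate 2 they lie at least as far apart as for the Mgea5 replicates (41.7% against 28.3%).

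The fourth comparison concerned the ends of protein-coding genes. Beyond the genes at the regions above, the highest Mgea5 folds at gene ends in both replicates were at the cap-binding gene Ncbp2 and its neighbour 0610012G03Rik (4.37 and 3.04), at Slc4a1ap and Supt7l (3.64 and 3.58), and at the autophagy gene Atg14 (3.50 and 3.62). Polr1c peaks marked the ends of Armc8 (14.7 and 12.2), the autophagy gene Atg13 with Harbi1 (14.7 and 11.8), Kansl3 (13.3 and 11.9) and the histone methyltransferase gene Setd1a (12.9 and 11.5). For Panx2 the genes with the highest folds were Peli1 (2.40 and 3.36), Ice1 (1.81 and 4.16), Ugt8a (1.85 and 3.95), Rc3h1 (1.90 and 3.84), Ap3b1 (1.76 and 4.12), Ppp2ca (1.72 and 4.18), Zfp982 (1.92 and 3.74), Thap2 with Zfc3h1 (2.11 and 3.34) and Syk (2.03 and 3.41). In replicate 1, each of these Panx2 peaks had a deposited −log10 q of 0.

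Of 21887 protein-coding genes, 14077 (64.3%) had Mgea5 peaks of both replicates within 1000 bp of an end, against 49.2% after shifts, and 114 (0.521%) had Polr1c peaks, against 0.0600% (one-sided permutation p = 0.001 for both). The Mgea5 excess of 15.1 percentage points was 6.39 under shifts of 20 to 200 kb (57.9% expected), 8.48 with windows of 2500 bp and 8.97 without replicate 1. The short list of replicate 1 set the Polr1c count, since replicate 2 alone had peaks at 3836 genes (17.5% against 5.64%). At 18 of the 114 genes the strongest peak of both replicates also lay at a gene transcribed by RNA polymerase III. Panx2 peaks were at 4401 genes (20.1% against 18.1%, permutation p = 0.001), but with windows of 2500 bp the share was below that after shifts (38.6% against 39.2%), without replicate 2 it was 23.6% against 27.4%, without replicate 1 it was 82.1% against 61.8%, and the call was lost under shifts of 20 to 200 kb (20.1% against 19.8%, permutation p = 0.14). At a q of at most 0.01 the genes numbered 55 for Mgea5, 73 for Polr1c and 0 for Panx2. Across genes, which are not independent replicates, the folds of the replicates had a Spearman rho of 0.126 for Mgea5, 0.00990 for Panx2 and 0.544 for Polr1c.

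At the genes of the 3 proteins themselves, Oga carried Polr1c peaks at its ends in both replicates (folds 3.63 and 5.74; −log10 q of 0 and 15.6) and Mgea5 peaks of 1.80 and 1.57. The Panx2 gene had no Panx2 peak in replicate 1, and its highest fold in replicate 2 was 2.3. The Polr1c gene had no Polr1c peak in either replicate, and the same held for Ogt, the gene of the enzyme that adds O-GlcNAc.

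Gene groups with more Mgea5 peaks at their ends than other genes were the replication-dependent histone genes and the ribosomal protein genes. Of the histone cluster genes, 63 of 67 (94.0%, against 64.2% of other genes) had Mgea5 peaks in both replicates (Fisher exact test, adjusted p = 3.64e-07), including H2ac11 and H4c9 (2.32 and 2.69), H4c12 (1.79 and 2.99) and H2ac23 (2.09 and 2.32). Of the ribosomal protein genes, 72 of 83 (86.7%) had them (Fisher exact test, adjusted p = 1.21e-04), including Rpl9 (2.88 and 2.43), Rps18 (2.68 and 2.39), Rplp0 (2.26 and 2.26) and Rpl7 (2.16 and 1.88). Solute carrier genes (250 of 337, exact adjusted p = 0.00127; highest at Slc1a1, 2.82 and 1.83, and Slc39a3, 2.15 and 2.36) and Zfp zinc finger genes (267 of 367, adjusted p = 0.00617; Zfp777, 2.66 and 1.81, and Zfp740, 2.01 and 2.31) were higher as well. Lower were the olfactory receptor genes (122 of 1106, 11% against 67.2%, exact adjusted p = 3.52e-313; highest at Olfr965, 1.62 and 2.72), the vomeronasal receptor genes (51 of 353, 14.4%, adjusted p = 3.05e-83; Vmn1r48, 1.94 and 2.25) and the clustered protocadherin genes (21 of 57, 36.8%, adjusted p = 4.63e-04; Pcdha4, 2.0 and 1.78). The protocadherin call was lost with windows of 500 bp (exact adjusted p = 0.167), without replicate 1 (59.6% against 71.3%, adjusted p = 0.169) and without replicate 2 (66.7% against 81.4%, adjusted p = 0.0664). With windows of 2500 bp its direction turned (89.5% against 81.3%, exact adjusted p = 0.368). The solute carrier call was lost with windows of 500 bp (exact adjusted p = 0.051) and without replicate 1 (0.0523). The Zfp call was lost with windows of 500 bp (exact adjusted p = 0.154) and without X, Y and chromosome 14 beyond 42 Mb (0.105). At a q of at most 0.01 few genes were left and no Mgea5 call held. These are two-sided Fisher exact tests with Benjamini-Hochberg adjustment over 87 tests, 29 lists for each of 3 proteins, and they treat neighbouring genes as independent.

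Panx2 peaks at gene ends were more frequent for the Zfp genes (99 of 367, 26.98% against 19.99%, exact adjusted p = 0.0136; Zfp982, 1.92 and 3.74, and Zfp143, 1.86 and 3.37) and the solute carrier genes (91 of 337, 27.0%, adjusted p = 0.0159; Slc25a1, 1.97 and 3.42, and Slc16a1, 1.76 and 3.39). They were less frequent for the olfactory (62 of 1106, 5.61%, exact adjusted p = 4.86e-43; Olfr860, 2.69 and 1.83) and vomeronasal receptor genes (28 of 353, 7.93%, adjusted p = 6.45e-09; Vmn2r114, 1.89 and 2.91). Without replicate 2 the olfactory call was lost (22.2% against 23.7%, exact adjusted p = 0.656) and the vomeronasal direction turned (28.05% against 23.55%, adjusted p = 0.219). Without replicate 1 the olfactory share was 25.3% against 85.2%. Among genes of at least 4 kb the olfactory call was lost too (exact adjusted p = 0.142). The Panx2 Zfp call was lost with windows of 500 bp (exact adjusted p = 0.0853) and without X, Y and chromosome 14 beyond 42 Mb (0.0622). The solute carrier call was lost with windows of 2500 bp (exact adjusted p = 0.47) and without replicate 2 (0.143). No Panx2 peaks of both replicates were at gene ends at a q of at most 0.01. Polr1c peaks were at 0 of 1106 olfactory receptor genes (against 0.549% of other genes, exact adjusted p = 0.0326). This call was lost with windows of 500 bp (exact adjusted p = 0.0731), at a q of at most 0.01 and among genes of at least 4 kb (adjusted p = 1 for both). In replicate 2 alone 10 of the 1106 had Polr1c peaks (0.904% against 18.4%, exact adjusted p = 5.26e-77). When the olfactory and vomeronasal receptor genes were left out of the background, the histone (exact adjusted p = 3.91e-05) and ribosomal protein lists (0.00349) stayed higher and the protocadherins lower (9.00e-05) for Mgea5, and the Zfp and solute carrier calls ended for both proteins. They also ended among genes of at least 4 kb. There the protocadherins stayed lower for Mgea5 (exact adjusted p = 0.0028), and the histone list could not be tested, since it kept fewer than 8 members. Of the ribosomal protein genes there, 27 of 30 (90.0% against 70.4%, exact adjusted p = 0.143) had Mgea5 peaks.

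The other lists did not pass the threshold, and the following counts are of genes with Mgea5 peaks and, after them, with Panx2 peaks. Of 23 neural progenitor genes, 17 and 2 had peaks, of 25 neuronal genes 17 and 9, of 14 astrocyte genes 10 and 2, of 15 oligodendrocyte genes 9 and 2, of 15 microglia genes 11 and 2, and of 14 endothelial and mural genes 10 and 1. Of 24 microRNA processing genes 18 and 5 had peaks, of 15 reported miR-9 target genes 12 and 2, of 14 O-GlcNAc and hexosamine genes 9 and 1, and of 22 connexin and pannexin genes 12 and 0 (exact adjusted p = 0.0783 for Panx2). The counts were 23 and 10 of 29 RNA polymerase I and ribosome biogenesis genes, 23 and 4 of 28 RNA polymerase III genes, 20 and 7 of 28 cell cycle genes, 15 and 6 of 18 immediate early genes, 17 and 6 of 23 Notch genes, and 26 and 6 of 30 Wnt genes (exact adjusted p = 0.073 for Mgea5). They were 21 and 5 of 30 long synaptic genes, 13 and 6 of 26 imprinted genes, 22 and 6 of 30 Polycomb and Trithorax genes, 31 and 4 of 39 Hox genes, 75 and 30 of 100 oxidative phosphorylation genes, and 30 and 11 of 39 proteasome genes. For Panx2, 14 of 67 histone genes, 24 of 83 ribosomal protein genes and 5 of 57 protocadherin genes had peaks.

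Polr1c peaks in both replicates were at a few members of these lists: Polr1d (5.18 and 3.52), a subunit gene of RNA polymerases I and III, the Wnt genes Wnt7a (3.34 and 4.62) and Fzd1 (3.85 and 2.0; 2 of 30, exact adjusted p = 0.0712), Emx2 of the neural progenitor list (3.34 and 4.85), Tut7 of microRNA processing (3.05 and 9.38), Oga, Atp5l (14.4 and 6.00) and Ndufs7 (7.40 and 3.48) of oxidative phosphorylation, Psma3 (6.53 and 6.45) and Psmc3 (6.82 and 5.72) of the proteasome, Rps29 (3.42 and 2.38), H4c8 (4.85 and 4.93), Zfp609 (7.38 and 10.3) and Slc39a6 (4.50 and 4.71). In replicate 1 the peaks at Wnt7a, Emx2, Tut7, Oga and Rps29 had a deposited −log10 q of 0. In replicate 2 it was 0.830 at Rps29 and 4.355 to 35.9 at the others, and 0.00137 at Fzd1. The peaks at Psma3, Ndufs7 and H4c8 were also at the tRNA genes n-TKctt17, n-TFgaa3 with n-TNgtt7, and n-TMcat9, and that at Rps29 was also at the 7SL RNA gene Rn7s1. The remaining lists had 0 members with Polr1c peaks in both replicates. Taken from replicate 2 alone, Polr1c peaks were more frequent at Notch genes (12 of 23, exact adjusted p = 0.00142) and Wnt genes (13 of 30, adjusted p = 0.00641).

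The last comparison was of gene classes, and tRNA genes stood out in the Polr1c lists. RNA polymerase III transcribes tRNA and 5S rRNA genes. Of 408 tRNA genes, 135 had a Polr1c peak in replicate 1, 163 in replicate 2 and 107 (26.2%) in both, against 0.00882% after shifts (permutation p = 0.001). At a q of at most 0.01 there were 68 (16.7%) in both. Median folds at the shared tRNA genes were 5.66 and 3.56, and the highest were at n-TLcag10 (chromosome 13, 23453432 to 23453514, folds 8.27 and 5.67), n-TAtgc9 (chromosome 11, 48834429 to 48834500, folds 9.14 and 4.80) and n-TKctt17 (chromosome 12, 70969120 to 70969192, folds 6.53 and 6.45). The vault RNA gene Vaultrc5 (7.40 and 5.61) and the 7SL RNA genes Rn7s1 (3.42 and 2.38) and Rn7s2 (4.46 and 2.56) had peaks in both replicates. Rn7sk (2.36) and Rmrp (3.06) had them in replicate 2 only, and Rnu6, Rpph1, Bc1, Rny1 and Rny3 in neither. Of these, Rpph1 lies on the sparse part of chromosome 14, where few peaks were called in any list.

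The set of RNA polymerase III genes fixed in advance held the 408 tRNA genes, 52 genes for 5S rRNA, Rnu6, Rn7sk, Rn7s1, Rn7s2, Rpph1 and Rmrp. Of these 466 genes, 112 (24.0%) had Polr1c peaks in both replicates, against 5 of 3570 other small RNA genes (0.140%; Fisher exact test, odds ratio 225.6, p = 2.34e-103). Without replicate 1 the counts were 200 and 60 (1.68%), and the odds ratio fell to 43.98 (exact p = 3.87e-150). It was 123.9 at a q of at most 0.01 and 354.4 without flanks. For Mgea5 the counts were 110 and 341 (odds ratio 2.93, exact p = 2.35e-16), with 90 tRNA genes (22.1% against 7.49% after shifts, permutation p = 0.001). For Panx2 they were 24 and 74 (odds ratio 2.56, exact p = 2.90e-04), with 15 tRNA genes (3.68% against 1.72%, permutation p = 0.018). Without replicate 1 this odds ratio was 1.31 (exact p = 0.00878). The exact tests of RNA polymerase III genes treat neighbouring genes, which can share a peak, as independent. The tRNA excess of 1.96 percentage points was 8.02 without replicate 1 (29.9% against 21.9%) and 3.94 without replicate 2 (11.8% against 7.82%). It was no longer past the threshold under shifts of 20 to 200 kb (two-sided permutation p = 0.12). At a q of at most 0.01, Mgea5 peaks were at 2 of the RNA polymerase III genes and Panx2 peaks at 0. Of the 52 genes for 5S rRNA, 17 had Mgea5, 9 Panx2 and 3 Polr1c peaks in both replicates (32.7%, 17.3% and 5.77%, against 7.56%, 1.61% and 0.0154% after shifts). The Polr1c count was set by replicate 1, since replicate 2 had peaks at 33 of the 52 (63.5% against 1.24%), 22 of them with a q of at most 0.01. For Panx2, replicate 2 had peaks at 45 and replicate 1 at 9, where the call was lost (two-sided permutation p = 0.06). For Mgea5, replicate 1 had them at 37 and replicate 2 at 20, where it was lost too (two-sided permutation p = 0.11). Under shifts of 20 to 200 kb the 5S calls of Panx2 (permutation p = 0.06) and Polr1c (p = 0.07) were lost. These copies share sequence, so reads may be placed among them arbitrarily. The same may hold for tRNA genes of the same anticodon. MicroRNA genes had Mgea5 peaks in 132 of 1228 cases (10.7% against 7.15%, permutation p = 0.001), Panx2 peaks in 24 (1.95% against 1.59%, p = 0.20) and Polr1c peaks in 3 (0.244% against 0.0106%, p = 0.002). Under shifts of 20 to 200 kb the Mgea5 share at microRNA genes stood against 9.07% (two-sided permutation p = 0.06), and without replicate 2 it was 36.8% against 23.6%. Without flanks 1 microRNA gene had Polr1c peaks (two-sided permutation p = 0.16), and in replicate 2 alone 31 had them (2.52% against 0.942%). Panx2 peaks were at 4.89% of microRNA genes in replicate 1 (against 7.43%) and at 41.9% in replicate 2 (against 21.2%).

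Mgea5 peaks touched 78.7% of protein-coding genes against 73.7% after shifts and 75.6% of lncRNA genes against 67.3% (permutation p = 0.001 for both). Under shifts of 20 to 200 kb these excesses of 5.04 and 8.28 percentage points fell to 1.26 and 1.38 (permutation p = 0.005 for both). Without replicate 1 the protein-coding excess was 2.64. Panx2 peaks of both replicates touched 54.1% of protein-coding genes against 55.2% (lower tail permutation p = 0.008) and 41.6% of lncRNA genes against 42.1%. Without replicate 1 the direction turned (87.1% against 80.1% and 86.4% against 75.5%, permutation p = 0.005 for both), and without flanks the two-sided permutation p for protein-coding genes was 0.06. Polr1c peaks touched 1.19% against 0.955% of protein-coding genes (permutation p = 0.002) and 0.464% against 0.325% of lncRNA genes (p = 0.005). For protein-coding genes the call was lost under shifts of 20 to 200 kb (1.19% against 1.17%, permutation p = 0.36). In replicate 2 alone 8906 protein-coding genes (40.7% against 27.2%) and 2545 lncRNA genes had Polr1c peaks. The snRNA genes, with 73 Mgea5, 17 Panx2 and 1 Polr1c cases of 1004, were not shown to differ from shifted windows for Mgea5 (permutation p = 0.71) or Panx2 (p = 0.58). Of 1340 snoRNA genes, 137 had Mgea5 peaks (10.2% against 7.66%, permutation p = 0.006; two-sided p = 0.11 without flanks; 31.0% against 25.0% without replicate 2). Panx2 peaks were at 33 (2.46% against 1.72%, permutation p = 0.042, two-sided p = 0.084) and Polr1c peaks at 1 (permutation p = 0.13).

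**Figure D4:**
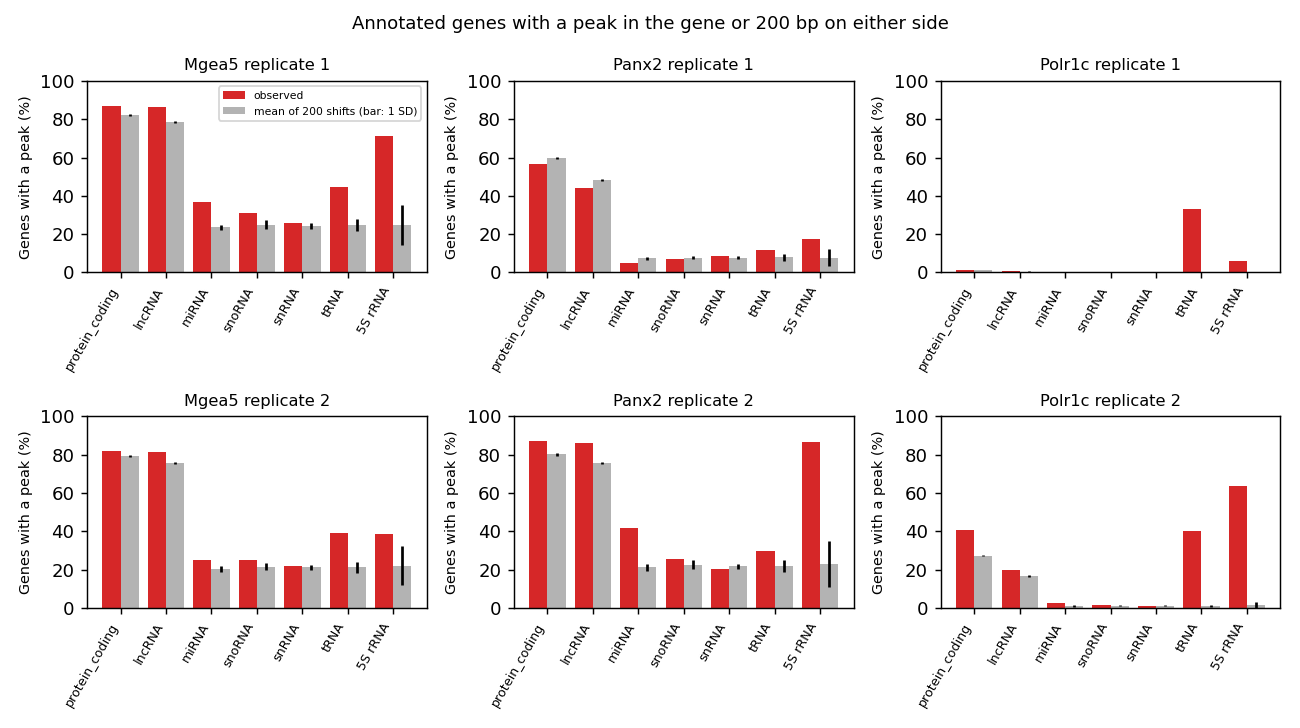
Share of annotated genes of each class with a peak in the gene or 200 bp on either side (y axis, percent), in a panel for each library, observed (red) and after 200 circular shifts (grey; bars, 1 SD). In the Polr1c panels the tRNA genes stand at 33.1% and 39.95%, far above their shifted values.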

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

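The tests of differences between proteins, and of the neighbourhood of tRNA genes, were chosen after the results were seen; the test of Mgea5 at tRNA genes with and without Polr1c was fixed before its result was seen.

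RNA polymerase III genes differed between proteins in how far they stood above other small RNA genes. The log2 odds ratio was 7.68 for Polr1c, 1.55 for Mgea5 and 1.38 for Panx2, so that Polr1c exceeded Mgea5 by 6.13 and Panx2 by 6.31 (permutation p = 0.0001 for each, the smallest that 10000 permutations can give). Without replicate 1 the log2 odds ratios were 5.45, 1.03 and 0.40 and the differences 4.42 and 5.05, and without replicate 2 the differences were 6.87 and 6.92 (permutation p = 0.0001 for each). Olfactory receptor genes were depleted in both broad lists, with a log2 odds ratio of -4.04 for Mgea5 and -2.14 for Panx2, a difference of -1.90 (permutation p = 0.0001). This difference turned with the replicate: it was 1.02 without replicate 1, where Panx2 stood at -4.08 and Mgea5 at -3.06, and -3.12 without replicate 2, where Panx2 stood at -0.12 (permutation p = 0.0001 for both). No direction of the difference between these proteins is therefore claimed. The permutations exchanged class labels between single genes, so they treat neighbouring genes as independent. They break the link of the class to both lists at once, so their p-values do not ask whether the class is linked equally to both. Peaks of the proteins were called in different layouts and numbers, so these differences compare lists and not binding strength.

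The excess of Mgea5 peaks at tRNA genes, 22.1% against 7.49% after shifts, was weighed further. Neighbourhoods rich in peaks are argued against as the whole cause, since the excess was 11.9 percentage points under shifts of 20 to 200 kb. Of the 107 tRNA genes with Polr1c peaks in both replicates, 38 (35.5%) carried Mgea5 peaks, against 52 of 301 others (17.3%), an odds ratio of 2.64 (Fisher exact p = 2.08e-04). That test treats neighbouring tRNA genes, which can share a peak, as independent. The higher share at tRNA genes with Polr1c peaks was followed no further. It may come from the same sites giving signal in both kinds of library, through presence of both proteins or through chromatin that is recovered or mapped more readily. No biological explanation was tested, and no value here separates these.

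Contigs outside the main chromosomes, which the comparisons left out, held peaks with a q of at most 0.01. Their number was 6 for Mgea5 replicate 1, 8 for Mgea5 replicate 2, 1 for Panx2 replicate 1, 7 for Panx2 replicate 2, 30 for Polr1c replicate 1 and 67 for Polr1c replicate 2. In Polr1c replicate 1, 36 of the 41 listed peaks on such contigs were on a single contig.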

How the results depend on the processing

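Alternatives that use shifts of 20 to 200 kb, libraries of 1 calling run, genes of at least 4 kb, or gene sets without receptor genes or sparse chromosomes, and those of the differences between proteins, were chosen after the data were seen. Of 299 alternative values for 55 results, 206 kept their direction and side of the threshold (counts and untested means were judged by size), 18 became weaker, 7 stronger, 23 moved and 45 changed sign. In 27 of the 45, neither value passed the threshold. Overlap of replicates for Mgea5 and Polr1c, overlap between proteins, and gene-end shares of Mgea5 and Polr1c kept their direction and side of the threshold under every alternative run, though the sizes moved. Comparing only libraries with the same replicate number (the replicate block) gave an excess of 5.48 percentage points for Mgea5 and Panx2, 23.2 for Mgea5 and Polr1c, and 28.6 for Panx2 and Polr1c, and ended no call; nothing shows that the numbers pair the libraries. Unless said otherwise, the cause of the changes below was not tested.

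Panx2 replicate overlap, below the shifted lists in all peaks, was above them by 99.9 percentage points at a −log10 q of at least 2, by 100 at 5 or more, and by 0.162 in lists of equal length. The Panx2 gene-end excess was -0.610 percentage points with 2500 bp windows, -0.00407 and -0.00400 at a −log10 q of at least 2 and 5, where no gene was left, 0.304 under shifts of 20 to 200 kb, and -3.79 to 20.3 when a replicate was left out.

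Counts of gene lists moved as follows. Mgea5 had 8 higher lists with 2500 bp windows, 0 higher and 0 lower at a −log10 q of at least 2 (few genes left), 0 higher among genes of at least 4 kb, where the histone list kept too few members to be tested, and 2 higher and 1 lower without receptor genes. The lower protocadherin call of Mgea5 was lost with either other window and without either replicate, each time leaving 2 lower lists. Panx2 had 1 higher list with 500 bp windows, 0 and 0 at a −log10 q of at least 2, 0 higher and 1 lower among genes of at least 4 kb, 0 and 0 without receptor genes, 1 higher without X, Y and chromosome 14 beyond 42 Mb, and 1 to 5 higher and 1 to 2 lower when a replicate was left out. Polr1c, whose lower list was that of olfactory receptors, had 0 lower lists with 500 bp windows, at a −log10 q of at least 2, among genes of at least 4 kb and without receptor genes, and 0 to 2 higher and 1 to 2 lower when a replicate was left out. The difference between Mgea5 and Panx2 in the log2 odds ratio of olfactory receptor genes was -3.12 to 1.02 when a replicate was left out, and so changed sign.

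Excesses of gene classes, in percentage points, moved for each protein. Leaving out a replicate gave, for Panx2, -3.29 to 6.96 for protein-coding, -4.24 to 10.9 for lncRNA, -0.308 to 5.23 for pseudogenes, -4.60 to 10.4 for other RNA, -2.54 to 20.7 for microRNA, -0.746 to 3.18 for snoRNA, -1.19 to 0.842 for snRNA and 9.65 to 63.6 for 5S rRNA genes. It gave 0.195 to 13.5 for protein-coding, 0.225 to 3.36 for lncRNA, -0.0503 to 0.0712 for snRNA and 5.75 to 62.2 for 5S rRNA genes for Polr1c, and 0.904 to 1.35 for snRNA and 16.4 to 46.2 for 5S rRNA genes for Mgea5. At a −log10 q of at least 2 the values were -0.00118 for Mgea5 at lncRNA, -0.00774 at microRNA, -0.00634 at snoRNA, -0.0692 at other RNA and 0 at 5S rRNA genes. They were -0.00262, -0.00285, -0.00187, -0.00735 and 0 for Panx2 at pseudogenes, microRNA, snoRNA, tRNA and 5S rRNA genes, and -0.00935, -0.133 and -0.00962 for Polr1c at pseudogenes, other RNA and 5S rRNA genes; hardly any genes were left there. Under shifts of 20 to 200 kb they were 1.26, 1.38 and 1.68 for Mgea5 at protein-coding, lncRNA and microRNA genes, 1.42 and 13.4 for Panx2 at tRNA and 5S rRNA genes, and 0.0245 and 5.12 for Polr1c at protein-coding and 5S rRNA genes. Without flanks, Polr1c at microRNA genes gave 0.0749, Mgea5 at snRNA genes 0.0503 and Panx2 at protein-coding genes -0.963.

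For miR-9 in Polr1c replicate 1, the mean percentile minus that of random sets was -0.0407 at the precursors, -0.204 within 1 kb, 14.9 within 50 kb and -0.244 at a −log10 q of at least 2, because its peak lies outside the narrow windows and above that q. No miR-9 value passed the threshold after adjustment over the 6 lists under any alternative run (lowest adjusted permutation p = 0.11), but signs changed. They did so at the precursors (0.733 for Mgea5 replicate 1, -1.75 for Panx2 replicate 1, -0.652 for Polr1c replicate 2), within 1 kb (-1.11, 7.68 and -3.42 for replicate 2 of Mgea5, Panx2 and Polr1c) and within 50 kb (-13.2 and 13.2 for replicate 2 of Mgea5 and Panx2). Ranked by the share of the window covered, Mgea5 replicate 1 gave 15.6. At a −log10 q of at least 2, Mgea5 replicate 2 and Panx2 replicate 1 gave -0.0407 and Polr1c replicate 2 -0.733. The mean percentile over both libraries, which was not tested, was 42.4 for Mgea5, 48.5 for Panx2 and 60.5 for Polr1c, and with a replicate left out it was 32.9 to 51.9, 40.1 to 56.9 and 54.9 to 66.2. Matching gene lists on GC content was not run, since no genome sequence was used here. Read depth is unknown, and peaks at a q of at most 0.05 numbered 175 and 181 for Mgea5, 15 and 1289 for Panx2 and 269 and 2424 for Polr1c.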

Other observations

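All tests in this part were chosen after the results were seen, except that of gene density.

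Mgea5 regions with a q of at most 0.01 in both lists often lay where the ends of neighbouring genes meet. Of the 41 such regions at an end of a protein-coding gene, 16 (39.0%) lay within 1000 bp of the ends of at least 2 genes, against 17.8% ± 5.97 (SD) for regions of the same widths placed at random gene ends (permutation p = 0.001). Examples are Tapbp and Rgl2, Ncbp2 and 0610012G03Rik, Supt7l and Slc4a1ap, and Ighmbp2 and Mrpl21 (chromosome 19, 3282072 to 3283289, folds 3.11 and 3.26). For Polr1c, 11 of 64 regions did so (17.2% against 15.5%, permutation p = 0.41). The difference between the proteins was not tested.

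Polr1c peaks of both replicates lay within 5 kb of 11 microRNA genes (0.896% of 1228 against 0.145% after shifts, permutation p = 0.016). Besides Mir9-3 with Gm51285, these were Mir5103 (folds 6.24 and 3.50), Mir762 (7.40 and 6.12), Mir7672 (7.40 and 7.91), Mir8105 (4.98 and 4.25, a peak that is also at the tRNA gene n-TScga2), Gm51269 (4.71 and 11.3), Mir497, Mir497b and Mir195a, which share a peak (3.92 and 2.47), and Mir101c (2.62 and 2.55), next to the regions at the start of chromosome 9 that are in all 6 lists.

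The low density of peaks on chromosome 14 beyond 45 Mb was weighed as a hypothesis about these cells. Low gene density is argued against, since 0% of the 137 other autosomal 5 Mb bins with as few genes were as sparse (median relative density 0.85, against 0.152 there). Removal of peaks after they were numbered is argued against too, since 0 peak numbers were missing. A filter of reads or regions before numbering would leave no gap, so it cannot be excluded. A candidate explanation is that a copy of this part is missing in the cells used: its density was 0.721 to 1.15 times that of the X chromosome, present once in male cells, in the 5 lists with enough peaks per bin. The input reads, which would decide this, were not analysed here.

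The Panx2 replicates shared no more positions than shifted lists, and they come from different calling runs. The Polr1c lists, split over the same runs, shared 48.0 times the expected overlap, and 24.5 times under shifts of 20 to 200 kb. They are narrow lists with 0.862% expected, against 28.5% for the broad Panx2 lists. They therefore cannot exclude an effect of the calling run on the Panx2 lists. Panx2 replicate 1 overlapped the other list of its run, Polr1c replicate 1, at a ratio of 4.48. Its ratios with the lists of run B lay between 0.985 and 1.12. The values are consistent with a replicate 1 list that holds few enriched regions: 0.0633% of its peaks had a −log10 q above 0, against 36.2% in replicate 2. No biological explanation was tested.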
